A study of Mus musculus with 11 samples.

How the data were processed

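RNA sequencing of germinal center B cells was taken from 1 deposited table with 1 column per library: 5 WT, 3 Crebbp-KO and 3 Ep300-KO libraries of cells sorted from mouse spleen 12 days after immunization with sheep red blood cells. Groups were taken from the sample labels. Per the labels, total RNA was made into libraries with TruSeq RNA v2, which does not keep strand, and the authors' processing notes name CASAVA 1.8, HISAT2, featureCounts and DESeq2 and the genome build mm10, without settings. The deposited signal values are gene read counts that the authors divided by 1 size factor per library (named DESeq2 normalized). Each column's values were whole multiples of 1 step within a tolerance of 1e-06 for 100% of values, so whole reads were recovered, and size factors recomputed with DESeq2 equalled the deposited ones. Depth per library is the sum of recovered reads. All 11 columns were used.

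Of 48593 genes, 22043 were 0 in every library, and 16515 with a mean of at least 10 were tested. The tests were limma 3.58.1 with a mean-dependent variance trend on log2(value + 1), in 1 fit with a mean per group and no covariate, two-sided, with Benjamini-Hochberg adjusted p below 0.05. All adjusted p values of genes come from limma unless another tool is named. Targeted genes also had exact two-sided permutation tests. Of 33 gene lists, 31 with at least 5 tested members were tested with limma camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry beside it. Neutrophil markers (0 tested genes) and NK cell markers (2 tested genes) were not tested as lists. Members were also adjusted over the list alone. Some lists share members, so their calls are not independent. Light zone genes overlap with NF-kB and CD40 response genes, for example, and dark zone genes with those of G2 and mitosis. Groups, tests, lists, the rule for naming genes and all alternatives but 3 were fixed before the data were examined; the 3 added later left out WT_46 with p300-KO_18, left out genes near Ep300, or took sex as a 2-level covariate. The rule named Crebbp and Ep300, then up to 8 genes per direction with the largest fold change among called genes whose libraries did not overlap and whose mean was at least 50 in the higher group, and up to 4 members of each described list with the smallest p. Predicted genes, pseudogenes, immunoglobulin and T cell receptor variable segments and sex-linked transcripts were left out of the second part, and some genes the rule named are not reported. Cbx7 and Apobec3 came in by this rule, and their neighbourhood was examined only after their values were seen.

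The correlation of the fold changes was compared with simulated unchanged groups, and shared changes with independent lists and with WT libraries split between the knockouts. No paired analysis was possible because the groups share no replicate numbers. Positions were taken from an annotation of GRCm38, the same build as mm10, for 99.4% of tested genes. Alternatives changed the pseudocount, the filter, the normalization, the variance model, library weights, the libraries fitted, a covariate for sex and the size threshold, left out each library in turn, and ran edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 were used.

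The procedure was tested on simulated data. At 1.5-fold, 2-fold and 4-fold changes it recovered 58.2%, 64.2% and 86.4% of changed genes in Crebbp-KO against WT. The shares were 50.7%, 58.2% and 83.3% in Ep300-KO against WT, and 31.3%, 61.2% and 86.4% in the direct comparison. False calls made up 4.79%, 3.76% and 4.80% of calls, and with no change 1, 0 and 0 genes were called. The simulation drew each gene independently, while genes of the real libraries move together, so these rates may not hold for the real data.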

Results

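RNA was measured in germinal center B cells of the mouse spleen, the B cells that proliferate, mutate their antibody genes and are selected after immunization. Mice were given sheep red blood cells, and 12 days later cells positive for B220, PNA and CD95 were sorted. The animals were wild type or lacked 1 of a pair of related lysine acetyltransferases, CREBBP or EP300, through a Cre that acts in germinal center B cells. There were 5 WT, 3 Crebbp-KO and 3 Ep300-KO libraries, named as labelled, where CBP-KO stands for Crebbp-KO and p300-KO for Ep300-KO. By their labels the WT mice were littermates from Crebbp crosses, and no WT mouse was labelled as a littermate of the Ep300-KO mice. In comparisons with Ep300-KO, a difference of cross or background therefore cannot be told apart from loss of Ep300. Sex, litter and batch were not given. The comparisons ask which transcripts differ between each knockout and WT, how the knockouts differ, and which changes they share. Group values below are normalized read counts as mean ± SD over 5 WT, 3 Crebbp-KO and 3 Ep300-KO libraries, and fold changes are on the log2(value + 1) scale.

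The depth recovered from the normalized counts was 85422179 reads in WT_4, 53550726 in WT_7, 82380484 in WT_41, 58018357 in WT_46 and 132861266 in WT_288. It was 63281823 in CBP-KO_1, 78385537 in CBP-KO_53 and 69955779 in CBP-KO_55, and 103858626 in p300-KO_18, 93137259 in p300-KO_287 and 59879689 in p300-KO_289. Of 48593 genes, 16515 had a mean of at least 10 and were tested. The first principal component held 21.4% of the variance, with WT_46 at -57.7 and the other WT libraries between -28.3 and -11.3. Immunoglobulin transcripts took 0.885% of the values in WT_46 and from 1.06% to 1.40% in the other 10 libraries. p300-KO_18 held Xist at 98751 and 4 Y-linked transcripts with a sum of 9852. Of the other 10 libraries, 6 held Xist at 149307 or more with a Y-linked sum of at most 11.1, and 4 held a Y-linked sum of 22498 or more with Xist at most 117. The latter 4 were WT_41, WT_288, CBP-KO_1 and p300-KO_287. The second principal component (18.4% of the variance) was higher in them than in the Xist-high libraries of the same group. It stood at 11.8 and 18.1 in WT_41 and WT_288 against -7.02 or lower in the other WT libraries. It was -0.446 in CBP-KO_1 against -36.3 and -40.2, and 47.1 in p300-KO_287 against 6.80 in p300-KO_289.

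The targeted genes were examined first. Ep300 (chromosome 15, 81585351 to 81652077) fell to 14466 ± 600.4 in Ep300-KO from 21268 ± 1276 in WT, a log2 fold change of -0.55 (limma adjusted p = 0.00015). Its lowest WT library stood at 19310.3 and its highest Ep300-KO library at 14828.9. An exact two-sided permutation test gave p = 0.0179, the smallest that 5 against 3 libraries allow. In Crebbp-KO, Ep300 stood at 23934 ± 1584 (log2 0.17, adjusted p = 0.111, exact permutation p = 0.0357). Crebbp (chromosome 16, 4081328 to 4213997) stood at 8247 ± 612 in Crebbp-KO and 8866 ± 743 in WT, a difference within the spread between replicates (log2 -0.10, adjusted p = 0.459, exact permutation p = 0.268). Reads were counted per gene and not per exon, so the Crebbp level does not check the Crebbp-KO labels. Crebbp stood at 10415 ± 471 in Ep300-KO (log2 0.24 against WT, adjusted p = 0.0551, exact permutation p = 0.0357).

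**Figure D1:**
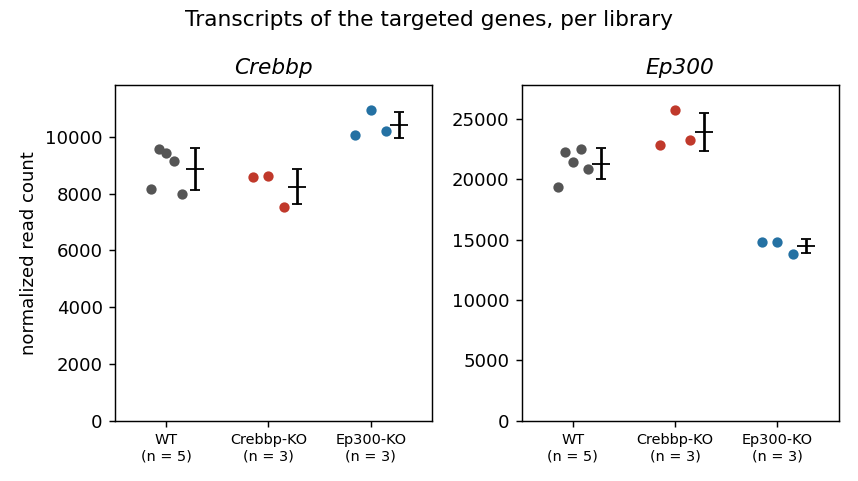
Normalized read counts of Crebbp and Ep300 in each library (points; 5 WT, 3 Crebbp-KO and 3 Ep300-KO), with the mean ± SD of each group beside the points. The 3 Ep300-KO libraries lie below every other library for Ep300, at 13772.8 to 14828.9, and the Crebbp-KO libraries overlap WT for Crebbp.

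In Crebbp-KO against WT, transcripts for MHC class II antigen presentation fell together. H2-Aa, the class II alpha chain of I-A, fell from 143972 ± 10838 to 88863 ± 12555 (log2 -0.70, adjusted p = 0.000693), and its partner H2-Ab1 from 148646 ± 8418 to 98497 ± 10195 (log2 -0.60). H2-Eb1 (log2 -0.63) and H2-DMa (log2 -0.66), part of the peptide-loading factor H2-DM, fell by similar amounts. Of 13 measured class II genes, 10 fell, 0 rose and 3 did not pass, and 13 were lower when adjusted over the list alone. The list was called lower (camera adjusted p = 4.15e-14), with adjusted p = 0.149 with an estimated correlation. The H2 genes are paralogs that can share reads, so single values are uncertain. Of 16 MHC class I genes 4 fell, 14 when adjusted over the list alone, with H2-T23, a nonclassical class I gene, at log2 -0.81. That list was also called lower (camera adjusted p = 9.46e-09; adjusted p = 0.245 with an estimated correlation). WT_46 had the highest value of the 11 libraries for the class I genes H2-Q7 (7625) and Tap1 (29825).

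**Figure D2:**
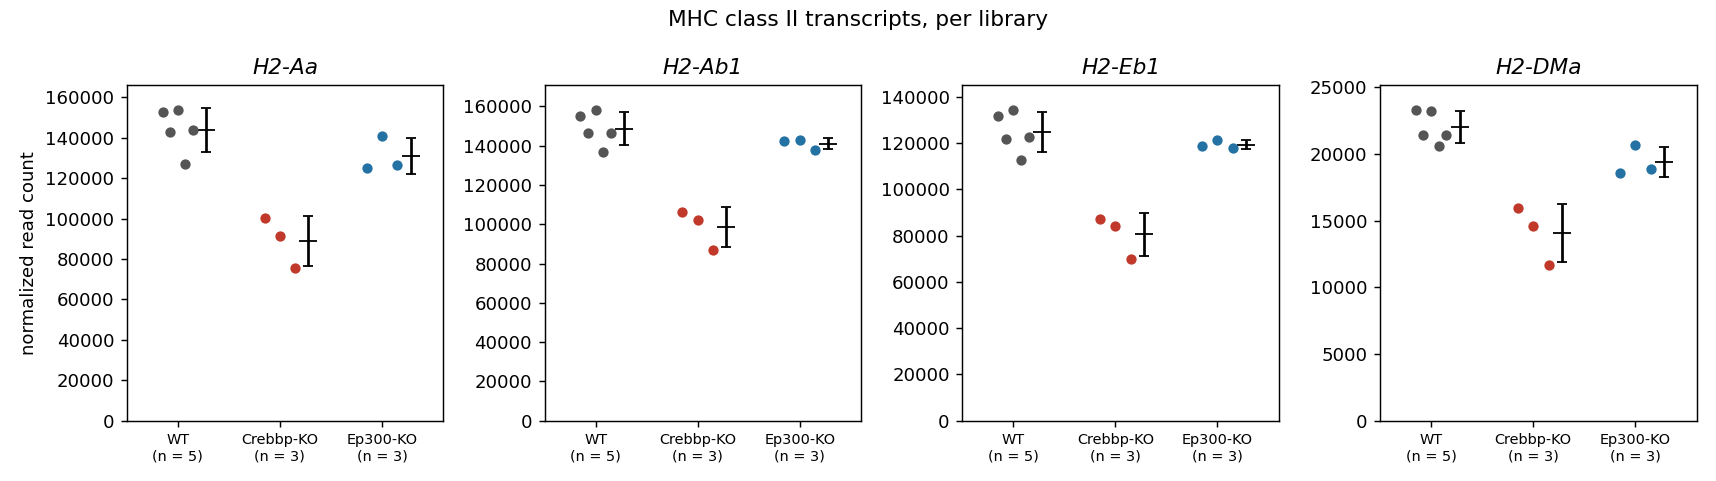
Normalized read counts of H2-Aa, H2-Ab1, H2-Eb1 and H2-DMa in each library (points; 5 WT, 3 Crebbp-KO, 3 Ep300-KO), with the mean ± SD of each group. Each Crebbp-KO library lies below every WT and Ep300-KO library for these 4 genes, with group means of 88863 for H2-Aa and 98497 for H2-Ab1.

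The list of light zone genes, named for the zone where B cells present antigen to T cells and receive signals, was also called lower in Crebbp-KO. Of 32, 14 fell and 1 rose, and 20 fell and 1 rose when adjusted over the list alone. Irf4, a transcription factor induced by CD40 and antigen receptor signals, fell from 3865 ± 431 to 2332 ± 311 (log2 -0.73). Nr4a1, an immediate response gene of antigen receptor signalling, fell from 925 ± 232 to 375 ± 32.7 (log2 -1.27), and Cd44 rose (log2 0.29). The light zone list had camera adjusted p = 2.52e-10, and adjusted p = 0.192 with an estimated correlation. Of 28 NF-kB and CD40 response genes 12 fell and 1 rose, 16 and 1 when adjusted over the list alone, with Nfkb2 at log2 -0.76, Relb at -0.67 and Traf1 at -0.57 (camera adjusted p = 1.56e-08; adjusted p = 0.149 with an estimated correlation). Of 17 cAMP and CREB response genes 7 fell and 0 rose, 10 and 0 when adjusted over the list alone. Junb (log2 -0.66), Per1 (-0.60) and Gem (-0.62) were among them (camera adjusted p = 6.89e-06; adjusted p = 0.149 with an estimated correlation). Traf1 and Relb are also members of the light zone list, and Nr4a1 is also in the cAMP list, so these list calls are not independent. Markers of macrophages and dendritic cells were lower in the same libraries, with the values given below.

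The lists of B cell receptor signalling and of positioning in the follicle were called lower too, with most members not past the test. Of 35 receptor signalling genes 11 fell and 1 rose, 16 and 1 when adjusted over the list alone, including the adaptor Sh3bp2 (log2 -0.80), Nfatc2 (-0.58), Vav2 (-0.31) and Inpp5d (-0.27). The list was called lower (camera adjusted p = 5.24e-07; adjusted p = 0.234 with an estimated correlation). Of 26 positioning and migration genes 7 fell and 1 rose, 13 and 2 when adjusted over the list alone. Rgs13, a regulator of chemokine receptor signalling, fell from 15914 ± 1622 to 4942 ± 2953 (log2 -1.84). This list was called lower (camera adjusted p = 0.00393; adjusted p = 0.323 with an estimated correlation). Of 27 naive and memory B cell genes 5 fell and 1 rose, 10 and 2 when adjusted over the list alone, with Dtx1, a regulator of Notch signalling, at log2 -0.71 and Cd200 at -0.55 (camera adjusted p = 0.00261; adjusted p = 0.428 with an estimated correlation).

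The lists higher in Crebbp-KO held few genes that passed alone. Of 22 p53 targets 6 rose and 1 fell, 7 and 1 when adjusted over the list alone, with Zmat3 at log2 0.61 and Ccng1, cyclin G1, at 0.41. The list was called higher (camera adjusted p = 0.0182; adjusted p = 0.192 with an estimated correlation), a call lost without CBP-KO_1 (adjusted p = 0.0821). Of 40 genes of G2 and mitosis 2 rose, 9 when adjusted over the list alone, with a median of 0.13 (camera adjusted p = 7.60e-08; adjusted p = 0.455 with an estimated correlation). Of 24 cholesterol synthesis genes Msmo1, a sterol demethylase, rose (log2 0.49), while 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.000331; adjusted p = 0.466 with an estimated correlation). Of 23 dark zone genes 2 rose and 1 fell, 3 and 1 when adjusted over the list alone (camera adjusted p = 0.00867; adjusted p = 0.406 with an estimated correlation). Bach2 rose (log2 0.37), with a call lost without CBP-KO_1 or CBP-KO_53 (adjusted p up to 0.101), and the gene that fell was Rgs13. The dark zone list shares mitotic genes such as Ccnb2 and Bub1 with the G2 and mitosis list.

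Of the lists of other cell types, those of macrophages, T cells, dendritic and stromal cells were called lower in Crebbp-KO than in WT, and the erythroid list was not called. Members of 1 list stood at unlike levels: every WT library held the T cell gene Lck at 8781.8 or more and Lat at 227.7 or less. Which cells these transcripts came from was not measured, so a lower list does not show fewer cells of that type. Of 19 macrophage and monocyte markers 7 fell and 0 rose, 10 when adjusted over the list alone, with a median of -1.29 (camera adjusted p = 5.40e-06; adjusted p = 0.192 with an estimated correlation). Mpeg1, perforin-2, stood at 1372 ± 311 against 3561 ± 1688, with 6428 in WT_46. Its call was lost without CBP-KO_53 (adjusted p = 0.0537). C1qb stood at 2.04 ± 1.97 against 37.7 ± 39.7, with 108 in WT_46 and at most 26.2 in the other WT libraries. Of 12 T cell genes 4 fell and 0 rose, 5 and 1 when adjusted over the list alone, with Lck (log2 -0.93) from 9718 ± 897 to 5100.0 ± 667 (camera adjusted p = 0.00141; adjusted p = 0.149 with an estimated correlation). Of 7 dendritic cell genes 2 fell, 3 when adjusted over the list alone, with Flt3 at log2 -0.60 (camera adjusted p = 0.0186; adjusted p = 0.192 with an estimated correlation; adjusted p = 0.0821 without CBP-KO_1). Of 6 stromal and endothelial genes Pecam1 (log2 -0.42) and Cdh5 (-0.87) fell, and 3 fell and 1 rose when adjusted over the list alone. That list's call (camera adjusted p = 0.0475; adjusted p = 0.192 with an estimated correlation) was lost whichever of the 11 libraries was left out (adjusted p up to 0.101).

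Single genes with the largest changes in Crebbp-KO are given next. Hmgcll1, a relative of HMG-CoA lyase, rose from 14.0 ± 1.67 to 124.8 ± 8.09 (log2 3.07 ± 0.28 SE), and Spry2, an inhibitor of receptor tyrosine kinase signalling, from 20.2 ± 7.40 to 129 ± 21.8 (log2 2.68). Slc25a24, Klhl23, Fgf13, Itga3, Jcad and Nav3 rose by log2 3.06, 2.97, 2.77, 2.32, 2.19 and 2.15. Fgf13 and Jcad did not pass without CBP-KO_53 or CBP-KO_55 (adjusted p up to 0.085 and 0.0972), nor Nav3 without CBP-KO_1 or CBP-KO_53 (up to 0.103). Sh2d1b1, an adaptor of SLAM family receptors, fell from 681 ± 187 to 79.6 ± 43.7 (log2 -3.25), and Btn2a2, a butyrophilin, from 196 ± 21.7 to 23.6 ± 11.7 (log2 -3.10). Tspyl5, Sytl3, Dnm3, Olfr98 and St8sia1 fell with log2 values of -4.31, -3.56, -3.11, -2.92 and -2.64. Ifi211 fell (log2 -3.58) with 376 in WT_46, and its call was lost without WT_4, WT_41, CBP-KO_1 or CBP-KO_53 (adjusted p up to 0.164).

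Across all genes, 1380 of 16515 changed in Crebbp-KO against WT by limma, 574 higher and 806 lower, of which 329 by 2-fold or more. The count was 658 without CBP-KO_53, 647 without CBP-KO_55 and 2730 with library weights. Of 31 tested lists 19 were called, 4 higher and 15 lower, and 0 were called with an estimated correlation, while fry, which tests whether the genes of a list move one way, called 12. Lists with shared members were each counted. Cytosolic ribosomal proteins (1 of 80 lower, 0 when adjusted over the list alone; camera adjusted p = 7.71e-08; adjusted p = 0.583 with an estimated correlation) were called lower with a median of -0.11. MYC targets and ribosome biogenesis (3 of 40 lower by either adjustment, including Odc1 at log2 -0.52; camera adjusted p = 0.000279; adjusted p = 0.593 with an estimated correlation) lost their call without CBP-KO_1 (adjusted p = 0.0988). Mitochondrially encoded genes had 0 of 33 past the test (camera adjusted p = 0.0407; adjusted p = 0.63 with an estimated correlation) and lost their call without WT_7, WT_46, WT_288, CBP-KO_53 or CBP-KO_55 (adjusted p up to 0.261). Quantile normalization ended the calls of the stromal (adjusted p = 0.0514) and mitochondrially encoded (0.087) lists, and a mean of at least 50 those of p53 targets (0.0591) and mitochondrially encoded genes (0.098). Not called were S phase, oxidative phosphorylation, glycolysis, interferon response, germinal center transcription factors, plasma cell genes, acetyltransferases and deacetylases, apoptosis regulators, DNA repair, immunoglobulin constant regions, erythroid genes, and immediate early and heat shock genes (adjusted p 0.0633 to 0.928).

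In Ep300-KO against WT, the lists of S phase and of DNA repair genes were called lower and those of plasma cell and immunoglobulin constant genes higher. These calls did not hold with an estimated correlation. Pold1, the catalytic subunit of DNA polymerase delta, fell from 26230.0 ± 761 to 19444 ± 1003 (log2 -0.43, adjusted p = 0.000259). Of 40 S phase genes 17 fell and 0 rose, 27 when adjusted over the list alone, with Cdt1 at log2 -0.40 and Rfc3 at -0.37. The list was called lower (camera adjusted p = 2.46e-13), with adjusted p = 0.692 with an estimated correlation. Of 34 genes of somatic hypermutation and DNA repair 7 fell and 1 rose, 10 and 2 when adjusted over the list alone. Hmces, which shields abasic sites, fell from 38111 ± 2185 to 24411 ± 1222 (log2 -0.64), and Lig4, the ligase of end joining, from 4835 ± 380.1 to 3050.0 ± 53.5 (log2 -0.66). That list was called lower (camera adjusted p = 0.00219; adjusted p = 0.692 with an estimated correlation), a call that ended with quantile normalization, as given below.

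Of 26 plasma cell genes 10 rose and 2 fell in Ep300-KO, 12 and 3 when adjusted over the list alone (camera adjusted p = 0.00104; adjusted p = 0.692 with an estimated correlation). Xbp1, the transcription factor of the secretory program, rose from 12082 ± 817 to 16852 ± 527 (log2 0.48). Hsp90b1, an endoplasmic reticulum chaperone, rose from 23458 ± 2589 to 36900.4 ± 4444 (log2 0.65), and Creb3l2 from 133 ± 21.9 to 476 ± 102 (log2 1.83). Cd93 fell from 459 ± 45.9 to 159 ± 20.1 (log2 -1.53). Of 12 immunoglobulin constant region genes 4 rose and 0 fell by either adjustment, with Ighe at log2 2.15, Igkc at 0.38 and the lambda genes Iglc1 at 0.65 and Iglc2 at 1.02 (camera adjusted p = 0.00455; adjusted p = 0.692 with an estimated correlation). The lambda constant genes are near-identical copies that can share reads, so their single values are uncertain.

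Of 29 transcription factors of germinal center B cells, 6 fell and 0 rose in Ep300-KO, 8 and 1 when adjusted over the list alone, and 23 did not pass. The list was called lower (camera adjusted p = 0.00455; adjusted p = 0.713 with an estimated correlation), a call that ended with quantile normalization (adjusted p = 0.138). Ets1 fell from 60867 ± 2419 to 44524 ± 1457 (log2 -0.45), Id3 from 5239 ± 767 to 2899.8 ± 93.0 (log2 -0.84), Tcf3, which encodes E2A, by a log2 of -0.35 and Foxp1 by -0.55. Of 35 B cell receptor signalling genes 8 fell and 1 rose, 10 and 1 when adjusted over the list alone, with the kinase Syk from 76582 ± 3381 to 49553 ± 3503 (log2 -0.63) and its adaptor Blnk at log2 -0.37. That list's call (camera adjusted p = 0.036; adjusted p = 0.713 with an estimated correlation) was lost without WT_4 (adjusted p = 0.051), WT_41 (0.094) or p300-KO_18 (0.0751). Of 17 cAMP and CREB response genes 5 fell by either adjustment, with Gem at log2 -0.54, Pde4b at -0.54 and Rgs2 at -0.42 (camera adjusted p = 0.037; adjusted p = 0.692 with an estimated correlation). The call was lost without WT_41 (adjusted p = 0.0544) or p300-KO_289 (0.105).

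The MHC class II list was not called in Ep300-KO (camera adjusted p = 0.103), and 0 of 13 genes passed limma over all genes or when adjusted over the list alone. H2-DMa stood at 19405 ± 1122 against 22008 ± 1189. The MHC class I list was called lower although 0 of 16 genes passed limma by either adjustment (camera adjusted p = 0.0171; adjusted p = 0.713 with an estimated correlation). Its member H2-Q7 stood at 1312 ± 89.0 against 3269.8 ± 2498 with 7625 in WT_46. Of 24 cholesterol synthesis genes 4 fell and 1 rose, 7 and 1 when adjusted over the list alone (camera adjusted p = 0.000611; adjusted p = 0.713 with an estimated correlation), with a median of -0.18. Mitochondrially encoded genes had a median of -0.40 with 1 of 33 lower by either adjustment (camera adjusted p = 0.000118; adjusted p = 0.713 with an estimated correlation). MYC targets (3 of 40 lower, 2 when adjusted over the list alone; camera adjusted p = 0.0421; adjusted p = 0.856 with an estimated correlation) lost their call without WT_4 (adjusted p = 0.308), WT_288 (0.077) or p300-KO_287, where the direction turned (0.988). Oxidative phosphorylation (1 of 63 higher and 2 lower, 1 and 1 when adjusted over the list alone; camera adjusted p = 0.0421; adjusted p = 0.856 with an estimated correlation) lost its call without WT_4 (adjusted p = 0.369) or p300-KO_287, where the direction also turned (0.268).

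Other lists were not called in Ep300-KO, though single members changed. Among macrophage markers, Apoe, which encodes an apolipoprotein, rose from 22618 ± 1539.8 to 37404 ± 2701 (log2 0.73), and Mpeg1 fell (log2 -1.18), a call lost without p300-KO_289 (adjusted p = 0.068). Of 19 macrophage markers 2 rose and 1 fell. Among T cell genes Thy1 rose from 44.2 ± 23.6 to 282 ± 129 (log2 2.73), while Lck (-0.89) and Ctla4 (-2.02) fell. Flt3 fell (log2 -0.86), as did the light zone gene Bhlhe40 from 813 ± 139 to 338 ± 47.6 (log2 -1.25). The chemokine gene Ccl22 rose (log2 2.24), and of 22 p53 targets 6 rose, among them Zmat3 (0.55) and Sesn2 (0.52), and 2 fell, among them Fas (-0.33), whose call was lost without p300-KO_289 (adjusted p = 0.0576). Not called were MHC class II, light zone, dark zone, G2 and mitosis, ribosomal proteins, glycolysis, NF-kB, interferon, positioning, naive and memory, acetyltransferase, apoptosis and p53 lists. The lists of T cells, macrophages, erythroid, dendritic and stromal cells and of immediate early genes were not called either (adjusted p over these 19 lists 0.0608 to 0.811).

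The largest single changes in Ep300-KO included neighbours of Ep300 itself. Apobec3, a cytidine deaminase that restricts retroviruses (chromosome 15, 79891659 to 79915906), fell from 41937 ± 1989 to 3583 ± 147 (log2 -3.55 ± 0.05 SE, adjusted p = 1.71e-13). Cbx7, a Polycomb protein whose annotated end overlaps that of Apobec3 (79915807 to 79971119), fell from 7310.0 ± 919 to 1340.2 ± 116 (log2 -2.44), and the library kit does not keep strand, so reads in the overlap cannot be assigned. Within 10 Mb of Ep300, 51 of 272 tested genes (18.8%) changed in Ep300-KO and 11.9% elsewhere, against 10.3% and 8.37% in Crebbp-KO. Slpi, a secreted protease inhibitor, rose from 2603 ± 588 to 17295 ± 2079.9 (log2 2.76). Nes, Klhl23, Kdelc2, Slc25a24, Kif13a, Pls3 and Gpx7 rose by log2 4.95, 3.69, 3.51, 3.34, 2.98, 2.80 and 2.74. C8a, Fam50b, Gpm6a, H2-Q2, Hbb-bt and Fam174b fell with log2 values of -2.95, -2.49, -2.48, -2.37, -2.29 and -2.24. Gpm6a stood at 1238 in WT_46, and H2-Q2 and Hbb-bt belong to gene families that can share reads.

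**Figure D3:**
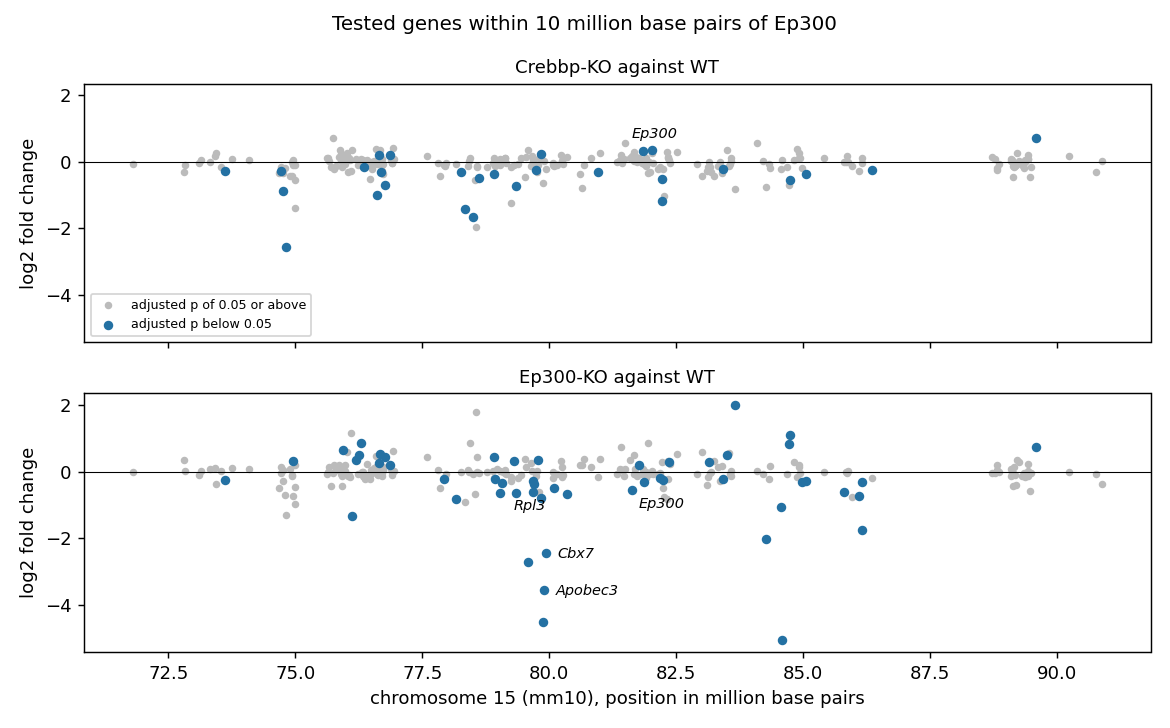
Log2 fold change of each tested gene within 10 Mb of Ep300 on chromosome 15, by position in Mb, in Crebbp-KO against WT (top) and Ep300-KO against WT (bottom); filled blue points passed limma at an adjusted p below 0.05. In Ep300-KO 51 of 272 genes passed, with Apobec3 at -3.55 and Cbx7 at -2.44.

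In total, 1970 of 16515 genes changed in Ep300-KO against WT by limma, 965 higher and 1005 lower, of which 417 by 2-fold or more. The count was 1260 without p300-KO_18, 1248 without p300-KO_287 and 1169 without p300-KO_289. Of 31 lists 12 were called, 2 higher and 10 lower, 0 with an estimated correlation and 6 by fry. With quantile normalization 6 of the 12 calls ended: MHC class I (adjusted p = 0.0782), MYC targets (0.369), oxidative phosphorylation (0.412), B cell receptor signalling (0.38), germinal center transcription factors (0.138) and DNA repair (0.0652). A mean of at least 50 ended those of MYC targets (adjusted p = 0.0622), oxidative phosphorylation (0.0622) and B cell receptor signalling (0.0535), and library weights those of MHC class I (0.106), MYC targets (0.306) and oxidative phosphorylation (0.899). Median, mean and test differed in sign for 5 lists that were not called: light zone, acetyltransferase, p53, erythroid and stromal genes. For p53 targets the median was -0.04 and the mean 0.05.

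**Figure D4:**
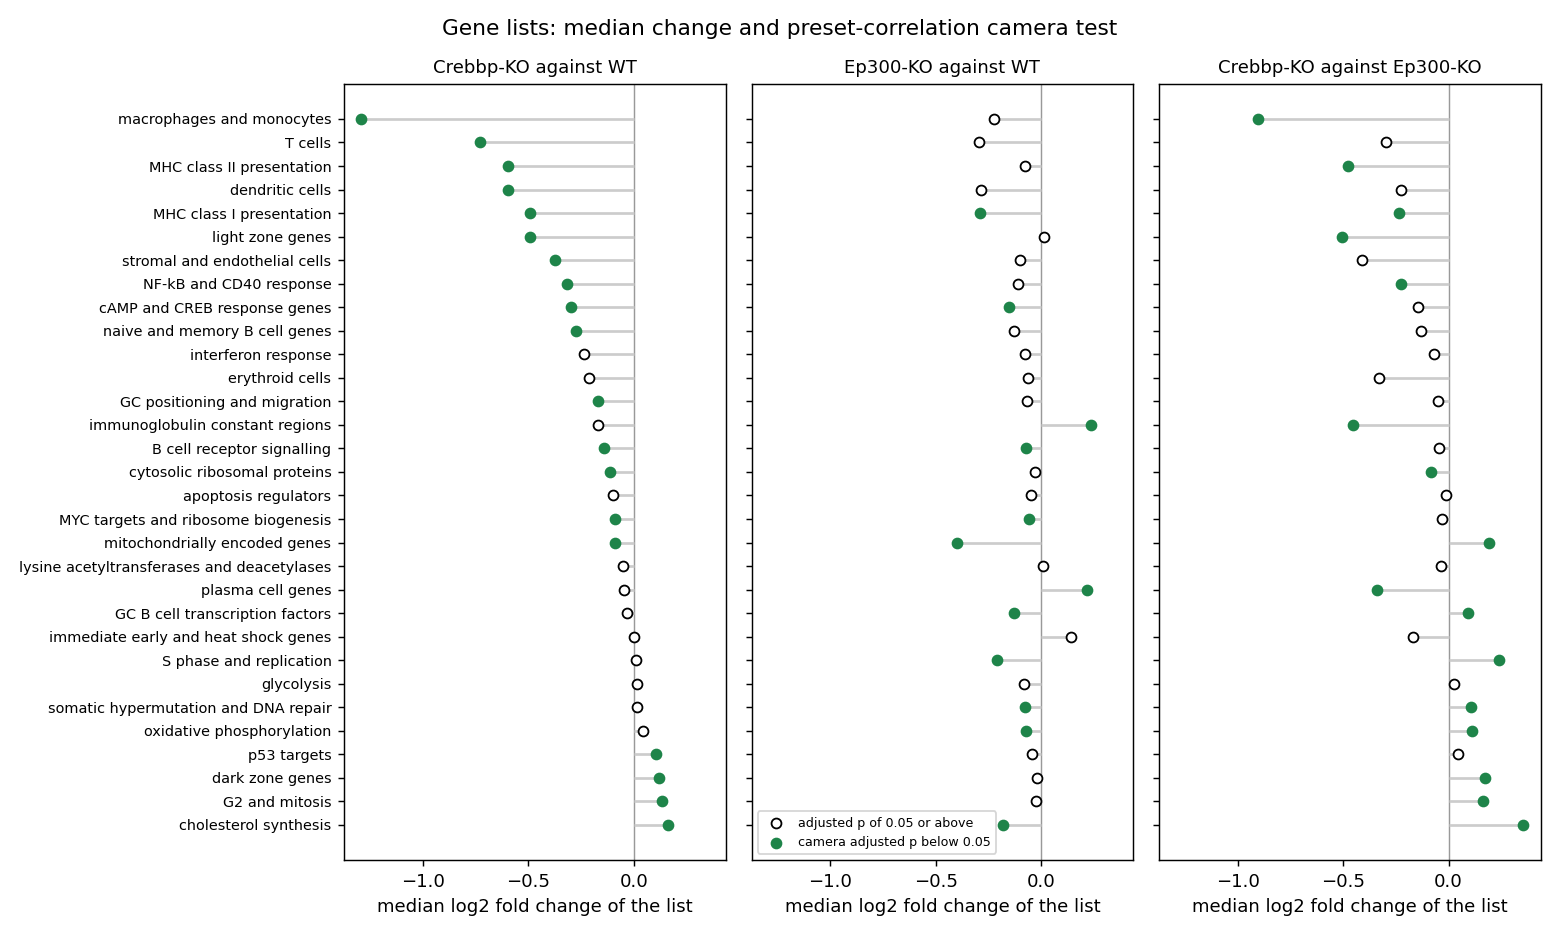
Median log2 fold change of each of the 31 tested gene lists in the 3 comparisons, ordered by the median in Crebbp-KO against WT; green points have a camera adjusted p below 0.05 with the preset correlation, and 0 lists pass with an estimated correlation. The MHC class II list has medians of -0.60, -0.07 and -0.48.

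The direct comparison of Crebbp-KO with Ep300-KO tests whether the groups differ, be it by genotype or by cross. The MHC class II and light zone lists were called lower in Crebbp-KO, with H2-Eb1 at 80555 ± 9225 against 119210.0 ± 1886 (log2 -0.57, adjusted p = 0.00158) and Myc, the growth regulator induced in selected cells, at 2958 ± 418 against 5417 ± 335 (log2 -0.88). Of 13 class II genes 8 were lower and 0 higher, 10 when adjusted over the list alone (camera adjusted p = 3.98e-09; adjusted p = 0.386 with an estimated correlation). Of 32 light zone genes 9 were lower and 2 higher, 17 and 2 when adjusted over the list alone, with Irf4 at log2 -0.82 and Cd44 at 0.61 (camera adjusted p = 2.98e-06; adjusted p = 0.386 with an estimated correlation). Of 28 NF-kB and CD40 genes 4 were lower, 5 when adjusted over the list alone, with Traf1 at log2 -0.42 (camera adjusted p = 0.000258; adjusted p = 0.386 with an estimated correlation). Of 16 class I genes 2 were lower by either adjustment, with H2-T23 at log2 -0.91 (camera adjusted p = 0.00879; adjusted p = 0.664 with an estimated correlation). Of 19 macrophage markers 4 were lower in Crebbp-KO, 10 lower and 1 higher when adjusted over the list alone, with Apoe at log2 -0.90 and Hmox1 at -1.02 (camera adjusted p = 0.000819; adjusted p = 0.399 with an estimated correlation).

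The plasma cell and immunoglobulin lists were also called lower in Crebbp-KO than in Ep300-KO. Of 26 plasma cell genes 14 were lower and 3 higher, 18 and 3 when adjusted over the list alone (camera adjusted p = 2.91e-06; adjusted p = 0.365 with an estimated correlation). Pdia4, a protein disulfide isomerase, stood at 3397 ± 181 against 7219 ± 906 (log2 -1.08), Hsp90b1 at 20536 ± 279 against 36900.4 ± 4444 (log2 -0.84), and Cd93 was higher (log2 2.18). Of 12 immunoglobulin constant genes 5 were lower and 0 higher, 7 when adjusted over the list alone (camera adjusted p = 5.84e-05; adjusted p = 0.365 with an estimated correlation). Ighe was lower (log2 -1.87), a call lost without CBP-KO_55 or p300-KO_287 (adjusted p up to 0.0616). The inhibitory receptor gene Cd22 was lower at 71550.5 ± 3932 against 115583 ± 4977 (log2 -0.69).

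The lists of replication, sterol synthesis and repair were called higher in Crebbp-KO than in Ep300-KO. Of 40 S phase genes 14 were higher and 0 lower, 26 when adjusted over the list alone, with Rpa3 at log2 0.48 and E2f1 at 0.40 (camera adjusted p = 3.85e-13; adjusted p = 0.395 with an estimated correlation). Of 24 cholesterol synthesis genes 11 were higher and 0 lower, 17 when adjusted over the list alone, with Msmo1 at log2 0.66 and Hsd17b7 at 0.59 (camera adjusted p = 3.78e-09; adjusted p = 0.386 with an estimated correlation). Of 34 repair genes 7 were higher, 12 higher and 2 lower when adjusted over the list alone, with Lig4 at log2 0.93 and Hmces at 0.81 (camera adjusted p = 0.00158; adjusted p = 0.419 with an estimated correlation). Of 23 dark zone genes 5 were higher, 9 when adjusted over the list alone, with Bach2 at log2 0.65, Foxp1 at 0.70 and Polh at 0.35 (camera adjusted p = 5.84e-05; adjusted p = 0.386 with an estimated correlation). Of 40 G2 and mitosis genes 6 were higher, 10 when adjusted over the list alone, with Cdc25b at log2 0.47 (camera adjusted p = 6.62e-08; adjusted p = 0.51 with an estimated correlation). Of 29 germinal center transcription factors 7 were higher and 1 lower, 8 and 1 when adjusted over the list alone, with Ets1 at log2 0.55 and Id3 at 0.71 (camera adjusted p = 0.0365; adjusted p = 0.638 with an estimated correlation). That call was lost without CBP-KO_1 (adjusted p = 0.263), p300-KO_18 (0.152) or p300-KO_289 (0.0573).

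Single genes separated the knockouts widely. Apobec3 stood at 42705 ± 1359 in Crebbp-KO and 3583 ± 147 in Ep300-KO (log2 3.58), and Myl4, a myosin light chain, at 5603 ± 568 and 829.8 ± 118 (log2 2.76). Nav3, Creg2, Fam50b, Rag1, Iglon5 and Epha2 were higher in Crebbp-KO by log2 4.34, 3.53, 3.50, 3.40, 2.85 and 2.82. Slpi stood at 2753 ± 258 against 17295 ± 2079.9 (log2 -2.65), and Myo1f, an unconventional myosin, at 197 ± 63.8 against 1017 ± 71.8 (log2 -2.42). Tspyl5 stood at 10.4 ± 8.58 against 84.4 ± 64.5. Nes, Lad1, Olfr98, Emilin2 and Entpd1 were lower with log2 values of -3.74, -2.55, -2.50, -2.45 and -2.40. Nes lost its call without CBP-KO_53, CBP-KO_55, p300-KO_18 or p300-KO_287 (adjusted p up to 0.0765), and Lad1 without CBP-KO_1, CBP-KO_55 or any 1 Ep300-KO library (up to 0.0885). Ep300 was higher in Crebbp-KO (log2 0.73), and Crebbp was lower (log2 -0.34, adjusted p = 0.0224), a call lost without CBP-KO_55 or p300-KO_287 (adjusted p up to 0.0968). An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, the value both targeted genes had.

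By limma, 1556 of 16515 genes differed between the knockouts, 791 higher and 765 lower in Crebbp-KO, of which 338 by 2-fold or more. The count was 863 without CBP-KO_53, 747 without CBP-KO_55, 849 without p300-KO_18 and 906 without p300-KO_287, and it was 2808 with library weights and 2350 with DESeq2. Of 31 lists 16 were called, 8 higher and 8 lower, 0 with an estimated correlation and 10 by fry. Ribosomal protein genes were called lower with a median of -0.08 and Rpl3 as the 1 member of 80 higher by either adjustment (camera adjusted p = 0.00184; adjusted p = 0.774 with an estimated correlation). The call was lost without CBP-KO_1 (adjusted p = 0.275) or p300-KO_18 (0.525). Oxidative phosphorylation was called higher with 1 of 63 members lower, 0 when adjusted over the list alone (camera adjusted p = 0.000177; adjusted p = 0.735 with an estimated correlation), a call lost without p300-KO_287 (adjusted p = 0.47). Mitochondrially encoded genes were called higher with 0 of 33 members past the test (camera adjusted p = 0.0328; adjusted p = 0.717 with an estimated correlation), and the call was lost without CBP-KO_1 (adjusted p = 0.222) or p300-KO_289 (0.294). A mean of at least 50 also ended the calls of germinal center transcription factors (adjusted p = 0.0682) and mitochondrially encoded genes (0.0682), quantile normalization that of germinal center transcription factors (0.227) and library weights that of mitochondrially encoded genes (0.064). The other 15 lists were not called (adjusted p 0.0717 to 0.782).

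Changes found in both knockouts against WT were compared last. Klhl23 (log2 2.97 in Crebbp-KO and 3.69 in Ep300-KO) and Slc25a24 (3.06 and 3.34) rose in both, and Dtx1 (-0.71 and -0.56), Lck (-0.93 and -0.89) and Odc1 (-0.52 and -0.33) fell in both. Cd44, Cd93, Lig4 and Rag1 changed in opposite directions, with Cd93 at log2 0.65 in Crebbp-KO and -1.53 in Ep300-KO. In all, 477 genes passed in both with the same direction, 256 higher and 221 lower, and 48 passed in opposite directions. Independent lists of these sizes would share 82.6 genes in the same direction. With the WT libraries split, so that each knockout had its own controls, 134 to 332 genes were shared over 20 splits, where independent lists would share 14.9 to 85.6. The shared count was 244 without CBP-KO_53, 254 without CBP-KO_55 and 297 without p300-KO_289, and it was 780 with library weights and 716 with DESeq2. Across genes, which are not independent replicates, the fold changes correlated at 0.427. That lies within the 0.319 to 0.437 (mean 0.377) that unchanged groups sharing a WT group gave over 100 simulated draws. The WT libraries were simulated too, so what the real ones contributed was not measured this way. With split WT libraries the correlation was 0.142 to 0.262. The covariance was 0.0890 against 0.0285 simulated, a difference of 0.0605, and 0.0367 to 0.0622 with split WT libraries. Genes were drawn independently, so the simulated ranges may be too narrow for real genes, which move together.

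**Figure D5:**
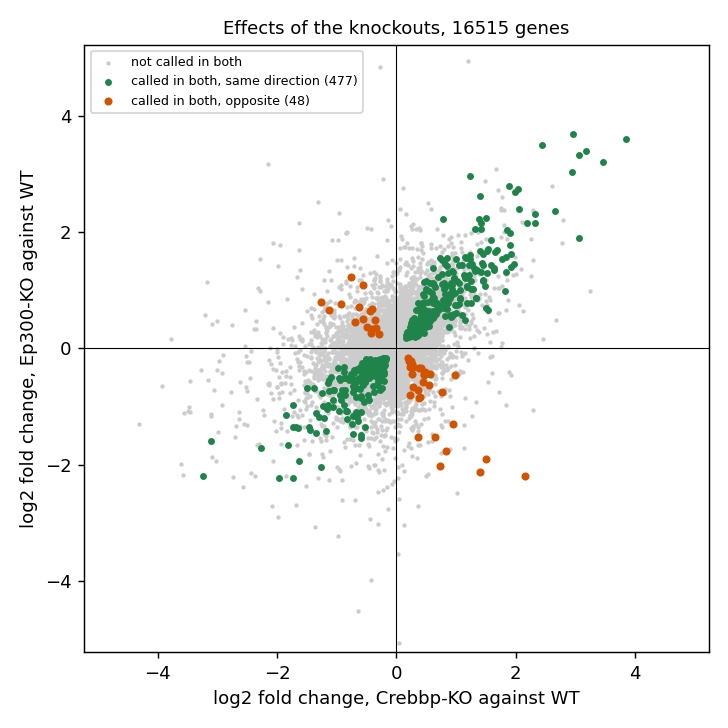
Log2 fold change in Ep300-KO against WT (vertical) by that in Crebbp-KO against WT (horizontal) for 16515 genes, with genes called in both knockouts in green (same direction, 477) or orange (opposite, 48). Simulated unchanged groups that shared a simulated WT group had a mean correlation of 0.377. The covariance of 0.0890 lay above the simulated maximum of 0.0341. Genes were drawn independently, so that maximum may be too low for genes that move together.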

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

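The splits of the libraries and the test of macrophage and dendritic cell markers were chosen in advance, and the other tests here only after the result was seen. Of 77 quantities examined in the WT group, 4 had 1 library far from the other 4. Chance gives about 1 in 20 groups such a library, a share that 4 of 77 does not clearly exceed. WT_46 had the lowest share of immunoglobulin transcripts, 0.885% (gap over range 0.751), though the highest WT mean of the immunoglobulin constant list (14.13 on the log2 scale), the highest mean of the macrophage list, 7.80 (0.733), and the highest Gpm6a, 1238 (0.866). WT_288 had the highest mean of the erythroid list (0.788), where the other WT libraries ran from 6.92 to 7.15. Of the 56 splits of the WT and Crebbp-KO libraries, only the real grouping itself gave as many called genes (1380), and the highest other gave 4. The same held for Ep300-KO, with 1 of 56 splits, 1970 genes and 4 in the highest other. Every other split put knockout and WT libraries in the same group, which widens the spread and lowers the count. The splits also cannot tell genotype from cross, litter or batch. For the direct comparison 1 of 10 splits gave as many (1556, highest other 3), and 10 splits are too few for a share under 0.05.

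Genes near Ep300 changed more often in Ep300-KO. Within 10 Mb, 51 of 272 genes were called and 11.9% elsewhere (Fisher exact p = 0.00125), while in Crebbp-KO the shares were 10.3% and 8.37% (p = 0.269, Fisher exact). Variants of another strain carried along with the targeted allele are a candidate explanation, and the level of Apobec3 is known to differ between inbred strains, but reads that could show such variants were not available. Rpl3, also near Ep300, fell from 97679.9 to 69400.2 while its pseudogene Rpl3-ps1, chosen after its values were seen, rose from 3045 to 23159, a gain of 71.1% of the loss, which may reflect reads passing between the copies, while the other copy, Rpl3-ps2, fell from 930.4 to 364. An effect of the loss of Ep300 on its neighbours stays open and untested.

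p300-KO_18 carried Xist and Y-linked transcripts together. Xist stood at 52.3% of the mean of the 6 libraries with high Xist and Y-linked transcripts at 41.5% of the mean of the 4 libraries with high Y-linked transcripts, together 93.8%, which is consistent with cells of a male and of a female mouse in 1 library. Admixture of cells from WT mice like those sequenced here is argued against by Apobec3. It differed in p300-KO_18 from the higher of the other Ep300-KO libraries by -293, where an admixture of this size needed an excess of 17414. Cells of the Ep300 cross that kept Ep300 are not covered, since their Apobec3 level was not measured. A single mouse with full levels of both is argued against by the same sum, while a single mouse with cells of both kinds stays open, since the labels give no sex.

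MHC class II transcripts were lower in Crebbp-KO. The summed fall of 26 macrophage and dendritic cell markers was 2.50% of the class II fall (8443 against 338301), where Apoe (22618), Ctsb (5551) and Flt3 (4651) have high WT levels. How much class II RNA such cells carry per marker was not measured. The share therefore cannot decide whether their RNA in the WT libraries contributed. Without WT_46, which had the highest macrophage list mean of the WT libraries, 10 of 13 class II genes were still called lower. Under quantile normalization 10 of 13 class II genes were still called lower, so these calls did not hang on the authors' size factors alone. The median change of all genes was log2 0.00645 with the authors' scaling and 0.0204 with quantile normalization. Both scalings take most genes as unchanged, so neither could show a change in total RNA. The quantile test replaced rescaling without immunoglobulin genes, which also left 10 and was judged void because these genes take about 1% of the values. Variants carried along with the Crebbp allele, on the chromosome of the class II regulator Ciita (log2 -0.35), cannot be told apart from loss of Crebbp. Near Crebbp 10 of 88 genes were called and 8.38% elsewhere (Fisher exact p = 0.331). Of 3 class II genes off chromosomes 16 and 17 Cd74 fell (log2 -0.51), while Rfx5 (-0.21) and Ifi30 (-0.70) did not pass over all genes (genes chosen after their values were seen). Both were lower when adjusted over the list alone, as were all 13 class II genes.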

How the results depend on the processing

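Leaving out both libraries that stood apart, leaving out the genes near Ep300 and sex as a 2-level covariate were chosen only after the result was seen. Over all alternatives, named genes kept direction and call in 6795 values, lost the call in 555, gained it in 6 and reversed in 0. Apart from Crebbp and Ep300, these genes were chosen for passing the main test, so their counts do not describe other genes. List calls held in 1008 values, were lost in 116 and reversed in 2, and the levels of Crebbp and Ep300 held in 30 of 30. These 30 include libraries left out of the other knockout, which cannot move the level tested. For Crebbp, held means that the difference stayed not past the test. Library weights gave 2730 genes for Crebbp-KO, 2808 for the direct comparison and 780 in both knockouts, and the cause was not tested. DESeq2 gave 2350 in the direct comparison, 716 in both and a correlation of 0.505, and the cause was not tested. A log2 fold change of at least 0.5 left 730, 953 and 768 genes by construction. Quantile normalization ended 9 list calls over the 3 comparisons and a mean of at least 50 ended 7. Quantile normalization left 6 lists in Ep300-KO, and the cause was not tested, nor was it for the estimated correlation, which left 0, 0 and 0 lists. A numeric covariate for sex, with all libraries kept, gave 1508 genes in the direct comparison, and sex as a 2-level covariate, with p300-KO_18 left out, gave 921, where leaving out that library alone gave 849. Without both libraries that stood apart the counts were 1407, 1377 and 1191, and without the genes near Ep300 1352, 1918 and 1508.

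With each library left out in turn, which lowers the number of samples, Crebbp-KO had 647 (without CBP-KO_55) to 1544 genes, Ep300-KO 1169 (without p300-KO_289) to 2035, the direct comparison 747 (without CBP-KO_55) to 1958, and both knockouts 244 (without CBP-KO_53) to 536. The correlation was 0.343 (without p300-KO_289) to 0.479 (without WT_288). In Ep300-KO, adjusted p ran from 0.00287 to 0.988 for MYC targets and from 0.000335 to 0.369 for oxidative phosphorylation. Both lists reversed without p300-KO_287 (0.988 and 0.268), and the cause was not tested. Depth ran from 53550726 to 132861266 reads, and no alternative tested its effect.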

Other observations

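All tests in this part were chosen only after the result was seen. Near Ep300, several genes outside the naming rule changed in Ep300-KO and are listed after their values were seen. Dmc1, a meiotic recombinase, fell (log2 -2.72), as did Parvb (-2.02), while Arhgap8 (1.10) rose, as did Scube1, from 8.27 to 31.4. Within 5 Mb of Ep300, 43 of 174 tested genes were called in Ep300-KO (Fisher exact p = 2.80e-06), and 22 of 174 in Crebbp-KO (12.6% against 8.36% elsewhere, Fisher exact p = 0.0529). Within 2 Mb, 20 of 85 genes were called in Ep300-KO, and 2 of 183 stretches of 85 neighbouring genes along the genome held as many. In Crebbp-KO 8 of 85 were called, and 75 of 183 stretches held as many.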
